A study of Ovis aries with 26 samples.

How the data were processed

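The series holds RNA sequencing of sheep oocytes and preimplantation embryos, 26 libraries in 8 stages. Oocytes at metaphase of the second meiotic division (MII, 2 libraries) and embryos made by in vitro fertilization and kept in culture were taken at the 2-cell (2C, 4 libraries), 4-cell (4C, 3), 8-cell (8C, 4) and 16-cell (16C, 3) stages, as morulae (Morula, 3), as early blastocysts (EarlyB, 3) and as expanded blastocysts (ExpB, 4). Per the labels, oocytes or embryos were lysed directly and poly(A) RNA was copied with Smart-seq2, a method that amplifies full-length cDNA from very small amounts of RNA. The labels give no number of oocytes or embryos per library, and nothing in them says whether replicates were separate animals, cultures or pools.

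The authors deposited a table of FPKM (fragments per kilobase of gene and per 1e6 assigned), 1 column per library, with 30186 genes and values to 4 decimals. Per the submitters' processing notes the tools were fastp 0.23.4, HISAT2 2.1.0, SAMtools 1.9 and featureCounts 2.0.1, with no role or order given. The genome build and the annotation are not given in the sources used here, and the table holds no positions, so genes are named by symbol only. Of the row names, 25921 occur in a sheep reference gene table and 25443 are symbols in it. As deposited, 3740 genes were at 0 in every library. The FPKM values of a library summed to between 419071 and 682165, so no further scaling to a common sum had been applied. Isoforms, splicing and poly(A) site use cannot be read from gene-level FPKM and were not analysed.

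Depth was not stated. It was recovered from the steps of the deposited FPKM values: low values of small RNA genes lie on multiples of the value that 1 read gives, which gives the number of reads behind each library's denominator. Between 99.7% and 100.0% of those values were whole reads within 0.05 reads, over values of up to 20 reads. Gene lengths were then searched so that each gene's values became whole reads. A length was found for 23557 of 23577 genes above 0 in at least 3 libraries, the recovered reads summed to 99.4% to 99.7% of the denominators, and 99.2% of 650 small RNA lengths equalled the reference table. The search was tested on simulated data in 2 ways. With random lengths and levels, 81.8% of 499 lengths were found exactly. With 499 genes drawn around real genes, whose lengths had come from the search itself, 100.0% were found, which is partly circular. A wrong length multiplies a gene's reads by the same factor in every library. Recovered reads were used for depth, for shares of reads and for 1 alternative fit. Assigned reads ranged from 16.0 to 35.6 per library in units of 1e6, and counting error is therefore small for all but genes near 0. Smart-seq2 reads carry no molecular identifiers, so reads are not independent molecules and a read count gives no sampling interval for molecules.

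Differences between stages were fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) of the deposited values, with lmFit on the 8 stage means over all 26 libraries, contrasts.fit and eBayes with an intensity trend (18 residual and 4.6 prior degrees of freedom). Genes with FPKM of at least 1 in at least 2 libraries were tested, 15766 in all. A gene was called changed, and is described as higher, lower, rising or falling, when its Benjamini-Hochberg adjusted p within the contrast was under 0.05 and its difference was at least 1 on the log2(FPKM + 1) scale, in limma's moderated two-sided test. No count model was used for the main results, because the table holds FPKM and not counts. The 8 contrasts were the 7 pairs of successive stages and 16C against 4C, which spans the window in which the embryonic genome of sheep is known to be activated. The p-values measure the spread between these libraries only, which may be technical.

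Before the data were examined, 17 lists of genes were written from general knowledge: oocyte and maternal-effect genes, genes known from zygotic genome activation, inner cell mass and pluripotency genes, trophectoderm genes, primitive endoderm genes, core spliceosome components, SR proteins with hnRNPs and other splicing regulators, cleavage and polyadenylation factors, factors of deadenylation, decay and storage of maternal RNA, DNA methylation and chromatin regulators, cytosolic ribosomal proteins, ribosome biogenesis factors, nuclear-encoded oxidative phosphorylation subunits, stress response and p53 target genes, and markers of cumulus and granulosa cells, of sperm and of blood cells. Lists were tested in each contrast with camera (limma), two-sided, at a preset inter-gene correlation of 0.01, and again with the correlation estimated per list. Benjamini-Hochberg adjustment covered all 136 tests. The camera test compares a list with all other tested genes, not its median with 0. With the preset correlation 47 tests passed 0.05, and 4 of them passed both ways. Members absent from the table were not analysed here, among them DPPA3, NLRP7, DUXA, LEUTX, KDM4E, TPRX1, TPRX2 and PABPN1, and 18 of the 76 oxidative phosphorylation subunits, most of them of complexes III and IV. Some genes stand on more than 1 list.

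Named genes followed a rule fixed before the data were examined: in each contrast, the 6 genes with the largest positive and the 6 with the largest negative difference among changed genes with a symbol whose values did not overlap between the stages, the 4 changed members of each list with the largest difference, and a fixed set of anchor genes at every stage. Any other gene is stated to have been chosen after its values were seen.

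The fit was tested on simulated data with 200 changed genes per contrast among 15766: between 82% and 91% of genes moved by log2 of 1.5 and between 98% and 100% of genes moved by 3 were recovered, with 2 to 15 unchanged genes called. In simulated lists, a shifted list reached p of 2.3e-37 or less, and 0 or 1 of 16 other lists fell under 0.05. The simulated genes varied independently of each other, so this cannot show how the list test behaves where members vary together. Genes detected per library (FPKM of at least 1) were compared between stages with a permutation test of the F statistic over 100000 resamples of the stage labels. Genes first detected after the 4-cell stage had FPKM under 1 in every MII, 2C and 4C library and at least 1 in every library of a later stage. Maternal genes no longer detected had at least 1 in every MII and 2C library and under 1 in every library of a later stage.

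Alternatives, fixed before the data were examined, were pseudocounts of 0.1 and 5, no filter, a filter on every library of a stage, rescaling to a sum of 1e6 (TPM scale), median-ratio scaling, quantile normalization, only the 2 stages of a contrast fitted, array weights, no intensity trend, adjusted p only, the replicate number as a block, and leaving out each library in turn. The fit to only the 2 stages kept the filter of all 26 libraries. When an MII library is left out, the lone MII sample is assumed to vary like the other groups. limma-voom on recovered reads was added after the data were seen. Other steps used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.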

Results

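Poly(A) RNA of 8 sheep stages was sequenced in 26 libraries. They were MII oocytes, 2-cell (2C), 4-cell (4C), 8-cell (8C) and 16-cell (16C) embryos, morulae, and early (EarlyB) and expanded (ExpB) blastocysts. Gene levels are FPKM, given as mean ± SD over the libraries of a stage, so that n is 2, 4, 3, 4, 3, 3, 3 and 4 in that order throughout. Differences are on the log2(FPKM + 1) scale, which understates the change of genes near or below an FPKM of 1. Reads assigned to genes, in units of 1e6, numbered 27.2 and 33.0 in the MII libraries and 30.4 to 35.6 in the 2C to 16C libraries. In the same units they numbered 25.9 to 30.4 in morulae, 16.0 to 19.9 in EarlyB and 19.3 to 25.4 in ExpB. Replicates need not be separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical.

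The first question was how alike libraries of the same and neighbouring stages were. Pearson correlations of log2(FPKM + 1) across tested genes, between libraries that are not shown to be independent, ran from 0.913 to 0.992 within stages. Between 8C and 16C libraries they ran from 0.873 to 0.955, and between 16C libraries and morulae from 0.727 to 0.852. There were 3 libraries with a slightly higher mean correlation with a neighbouring stage than with their own: 4C 1 and 4C 2 with 2C (0.972 and 0.98) and 16C 1 with 8C (0.95). The library 16C 3 correlated at 0.913 and 0.923 with 16C 1 and 16C 2, which correlated at 0.962 with each other. The share of reads on 13 mitochondrial protein genes was 0.534% to 1.81% from MII to 16C, 3.82% to 5.10% in morulae, 8.39% to 9.92% in EarlyB and at least 8.94% in ExpB.

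**Figure D1:**
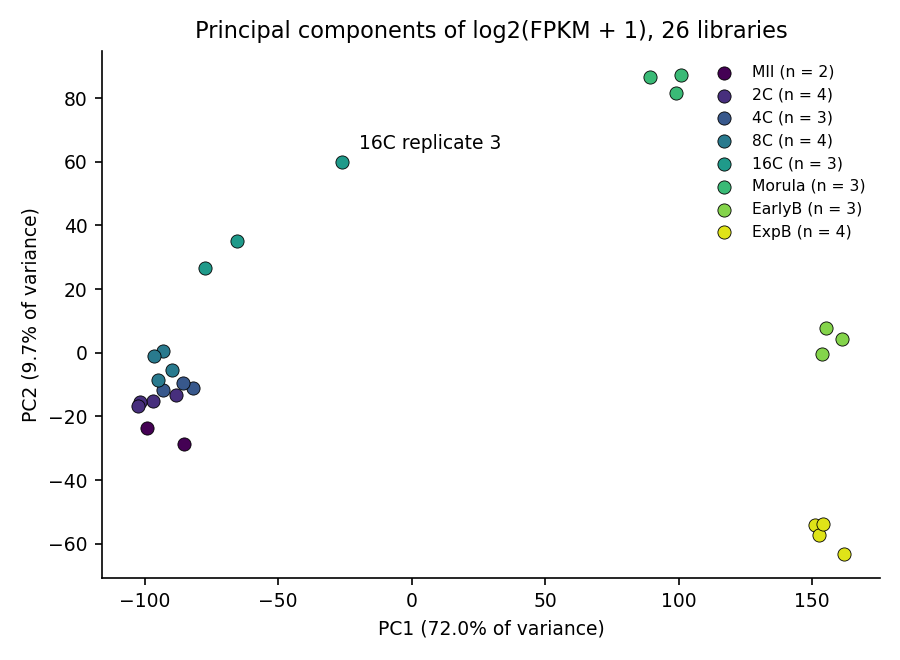
Principal components of log2(FPKM + 1) over the 15766 tested genes, 1 point per library, coloured by stage, with the share of variance on each axis. The first component (72.0% of the variance) parts the MII to 16C libraries from morulae and blastocysts, and the second holds 9.7%.

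When transcripts appear and disappear was first asked gene by gene. Genes at an FPKM of at least 1 numbered 8570 ± 105 per library in MII oocytes, 9212 ± 253 at 2C, 9457 ± 87 at 4C, 9713 ± 129 at 8C and 9796 ± 98 at 16C. Their number was 11575 ± 113 in morulae, 12104 ± 39 in EarlyB and 10605 ± 265 in ExpB. The count also rose from 8C to 16C at an FPKM of at least 5 (5822 to 5847). It fell at 0.1 (14646 to 14252) and on the TPM scale (11688 to 11544, ExpB 11722). The stages differed (permutation test of the F statistic, p = 1e-05, the smallest that 100000 resamples can give). Of 2911 genes below 1 in every MII, 2C and 4C library and at 1 or more in every library of a later stage, 33 reached it at 8C (55 without 4C 3, 70 without 8C 1), 135 at 16C (258 without 16C 1, 226 without 16C 3), 1353 in morulae, 1172 in EarlyB and 218 in ExpB. Among those first detected at 16C were the zygotic activation genes KLF17, OTX2, TBX3, KDM5B and SLC34A2, the pluripotency genes PRDM14 and ZFP42, the trophectoderm factor TFAP2C and the primitive endoderm factor GATA6. NANOG, ESRRB, KRT18, TEAD4 and DUXB followed in morulae, and SOX2, UTF1, CDX2, KRT19 and HAND1 in EarlyB. Of 7629 genes at 1 or more in every MII and 2C library, 1232 fell below 1 in every library of a later stage, among them 348 in morulae, 420 in EarlyB and 412 in ExpB. The oocyte genes NLRP5 (16C), ZAR1 and FIGLA (morulae), ASTL and PATL2 (EarlyB) and ZP3, NPM2, WEE2 and PADI6 (ExpB) were among them. These are counts against a threshold, with no test.

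**Figure D2:**
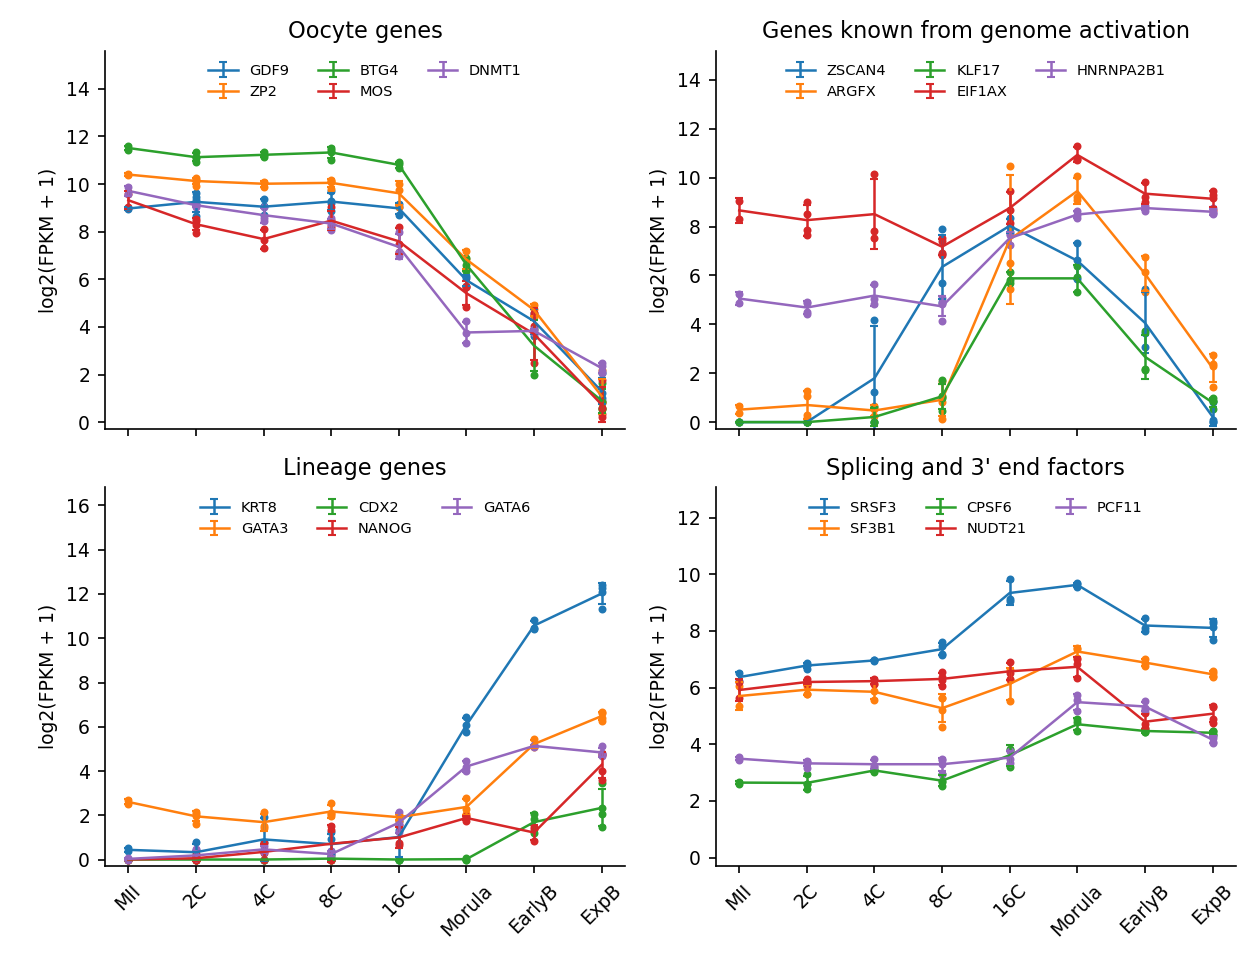
Levels of 20 anchor genes as log2(FPKM + 1) against stage in 4 panels, with points for libraries, lines through stage means and bars of 1 SD. Mean FPKM of BTG4 was between 1794 and 2923 from MII to 16C and 97.9 in morulae, that of ZSCAN4 was highest at 16C with 263, and that of KRT8 reached 4313 in ExpB.

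Compared with MII oocytes, 700 genes were higher and 317 lower at 2C. Poly(A) tail length was not measured at any stage, so these need not be changes in total RNA. PTCD2, a mitochondrial pentatricopeptide repeat protein, rose from 4.08 ± 0.252 to 43.2 ± 12.5 (adjusted p = 3.9e-07), the zinc finger gene ZNF134 from 4.25 ± 2.32 to 31.2 ± 1.75 (adjusted p = 4.2e-06) and UTP11, a ribosome assembly factor, from 76.4 ± 27.0 to 456 ± 7.95 (adjusted p = 6e-05). Among the genes that fell were ZFP36L1, which promotes the decay of AU-rich mRNA, from 176 ± 81.7 to 15.0 ± 2.81 (adjusted p = 3.9e-07), the transcription factor SP2, from 12.7 ± 2.44 to 0.770 ± 0.147 (adjusted p = 2.7e-07), and SPDYC, an activator of cyclin-dependent kinases, from 9.18 ± 0.746 to 0.397 ± 0.166 (adjusted p = 0.0008). Also higher were LUM, an extracellular matrix proteoglycan, from 4.39 ± 1.39 to 103 ± 65.6, and GSTA1, from 0.0802 ± 0.113 to 13.4 ± 7.30. The calls of LUM and GSTA1 ended without MII replicate 1 (adjusted p = 0.21 and 0.15) and without MII replicate 2 (adjusted p = 0.12 and 0.063), and that of LUM without 2C replicate 2 (adjusted p = 0.062), and both ended with limma-voom on recovered reads (adjusted p = 0.1 and 0.081). LUM is the called member of 16 cumulus and granulosa cell markers (1 and 0 adjusted over the list alone, 0.3 in the median, camera adjusted p = 0.78, and adjusted p = 0.95 with an estimated correlation), and SRGN, outside that list and chosen after its values were seen, stood at 4.4 and 8.13 in the MII libraries and 38.6 to 140 at 2C. Also lower were SEC61G, from 1212 ± 978 to 162 ± 74.0, and TACC3, from 371 ± 336 to 53.2 ± 23.6, whose calls ended without MII replicate 1 (adjusted p = 0.2 and 0.19).

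Among 76 tested cytosolic ribosomal protein genes there were 1 higher and 17 lower (1 and 29 adjusted over the list alone). At 2C the ribosomal protein median difference was -0.94 (camera adjusted p = 4.4e-19, and adjusted p = 0.39 with an estimated correlation). RPL37 went from 451 ± 414 to 69.2 ± 31.4 and RPS12 from 80.7 ± 65.2 to 15.7 ± 9.96, and both calls ended without MII replicate 1 (adjusted p = 0.41 and 0.44). The 69 ribosome biogenesis factors included 8 higher and 0 lower (8 and 0 adjusted over the list alone). At 2C the biogenesis factor median difference was 0.29 (camera adjusted p = 0.083, and adjusted p = 0.78 with an estimated correlation). Besides UTP11, POLR1E, a subunit of RNA polymerase I, rose from 7.23 ± 0.643 to 25.6 ± 3.66. Of 58 oxidative phosphorylation subunits 7 were higher and 5 lower (7 and 6 adjusted over the list alone), with a median difference of -0.1 that was 0.07 on the TPM scale (camera adjusted p = 0.81, and adjusted p = 0.99 with an estimated correlation). The complex I subunits NDUFA8, from 42.4 ± 12.7 to 205 ± 15.5, and NDUFS7, from 2.35 ± 1.42 to 15.1 ± 0.640, were among the higher ones. Of 56 chromatin regulators there were 2 higher and 7 lower (3 and 7 adjusted over the list alone). At 2C the chromatin regulator median difference was -0.09 (camera adjusted p = 1e-04, and adjusted p = 0.11 with an estimated correlation). TRIM28, a corepressor of KRAB zinc finger proteins, fell from 18.4 ± 3.89 to 6.0 ± 0.723.

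Core spliceosome components (85 tested) had 5 members higher and 12 lower (6 and 13 adjusted over the list alone), with a median difference of -0.06 that was 0.05 on the TPM scale (camera adjusted p = 0.028, and adjusted p = 0.66 with an estimated correlation). That list's call ended on the TPM scale (adjusted p = 0.2) and without MII replicate 1 (adjusted p = 0.26). SF3B4 of the U2 particle fell from 144 ± 6.77 to 34.7 ± 14.1. The SR protein SRSF1, which guides the choice of splice sites, rose from 4.60 ± 0.470 to 12.2 ± 2.08, in a list of 67 splicing regulators with 4 higher and 1 lower (5 and 1 adjusted over the list alone) and a median of 0.06 that was -0.15 with median-ratio scaling and -0.02 with quantile normalization (camera adjusted p = 0.49, and adjusted p = 0.87 with an estimated correlation). Trophectoderm genes (36 tested) had 2 higher and 1 lower (2 and 1 adjusted over the list alone). At 2C the trophectoderm median difference was -0.04 (camera adjusted p = 0.028, and adjusted p = 0.5 with an estimated correlation). That call ended with median-ratio scaling (adjusted p = 0.06) and without MII replicate 1 (adjusted p = 0.13).

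The oocyte list (34 tested) had 1 higher and 4 lower (1 and 4 adjusted over the list alone). At 2C the oocyte median difference was -0.41 (camera adjusted p = 3.4e-05, and adjusted p = 0.4 with an estimated correlation). Among the called oocyte genes were FIGLA, a germline transcription factor, from 20.2 ± 3.8 to 5.78 ± 0.700, KPNA7, an oocyte importin, from 2299 ± 1097 to 884 ± 95.4, ACCSL, from 1563 ± 833 to 523 ± 32.0, and BMP15, an oocyte growth factor, from 87.4 ± 35.9 to 259.5 ± 46.1. These 4 calls ended without MII replicate 1 (adjusted p = 0.24, 0.64, 0.43 and 0.55). Those of KPNA7 and BMP15 ended also without 2C replicate 2 (0.052 and 0.066) or 2C replicate 3 (0.064 and 0.074), that of KPNA7 without 2C replicate 1 (0.061) and that of BMP15 without 2C replicate 4 (0.082). CNOT1, the scaffold of the deadenylase complex, rose from 5.99 ± 1.96 to 18.9 ± 2.73, while the decay and storage list as a whole (59 tested) had 2 higher and 3 lower (2 and 3 adjusted over the list alone, camera adjusted p = 0.43, and adjusted p = 0.73 with an estimated correlation). None of 21 tested zygotic activation genes was called (0 adjusted over the list alone, 0.08 in the median, camera adjusted p = 0.43, and adjusted p = 0.71 with an estimated correlation), and ZSCAN4 and KLF17 were listed at 0 in every MII and 2C library.

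Without MII replicate 1 the fit called 212 genes, 161 higher and 51 lower. The split depended on the scaling of the libraries: 1332 higher and 292 lower on the TPM scale, where the median of all genes moved from 0.07 to 0.17, 415 and 602 with median-ratio scaling, and 361 and 443 with quantile normalization. With quantile normalization KPNA7, ACCSL, BMP15 and SRSF1 were no longer called, on the TPM scale KPNA7 and with median-ratio scaling BMP15. When only these 2 stages were fitted SEC61G, TACC3, RPL37, RPS12, ACCSL and KPNA7 were no longer called.

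**Figure D3:**
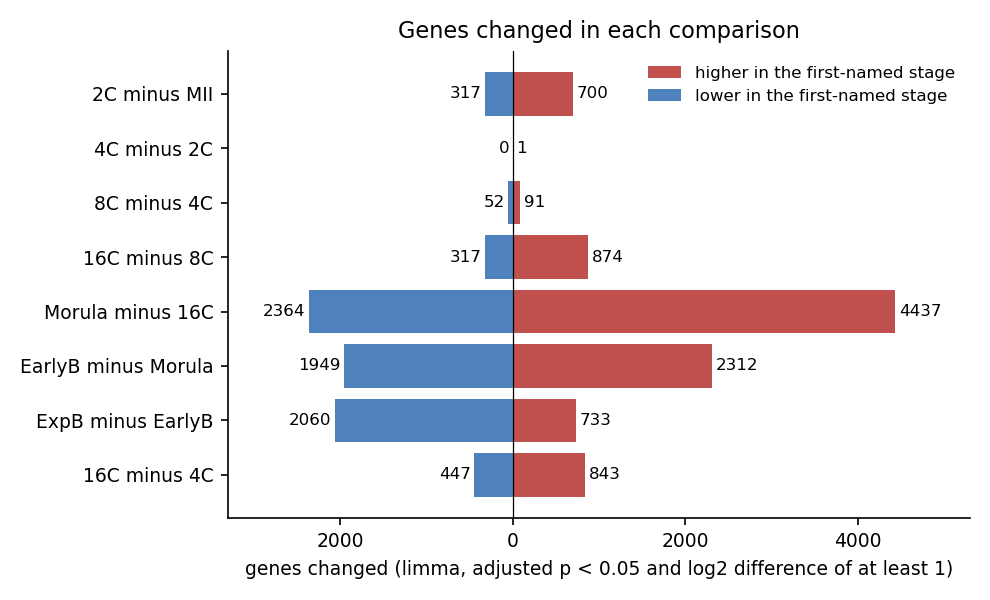
Numbers of genes called higher (red, to the right of 0) and lower (blue, to the left) in the first-named stage of each contrast, out of 15766 tested. The counts are 1 and 0 for 4C minus 2C, 4437 and 2364 for Morula minus 16C, and 733 and 2060 for ExpB minus EarlyB.

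Between 2C and 4C embryos, the stages before the known window of genome activation in sheep, a single gene was called. It was the transfer RNA gene TRNAS-GGA_55, listed at 0 in every 2C library and at 5.00 ± 1.68 at 4C (adjusted p = 0.00056), a gene chosen after its values were seen. ZSCAN4, a marker of genome activation, was listed at 0 in every 2C library and at 6.11 ± 9.46 at 4C and was not called (adjusted p = 0.45). Of the oocyte genes BTG4, an adaptor of the deadenylase complex, was at 2247 ± 263 and 2399 ± 185, GDF9 at 627 ± 163 and 538 ± 124, and the zona pellucida gene ZP2 at 1120.0 ± 106 and 1034 ± 87.9. No ribosomal protein gene was called, and the list of 76 lay higher at 4C with a median difference of 0.55 (0 and 0 adjusted over the list alone, camera adjusted p = 4.6e-12, and adjusted p = 0.51 with an estimated correlation). The 34 oocyte genes lay lower with a median of -0.23 and 0 called (0 and 0 adjusted over the list alone, camera adjusted p = 0.00011, and adjusted p = 0.46 with an estimated correlation). SR proteins, hnRNPs and other splicing regulators (67) lay higher by a median of 0.14 with 0 called (1 and 0 adjusted over the list alone, camera adjusted p = 0.00027, and adjusted p = 0.31 with an estimated correlation). The 16 cumulus and granulosa cell markers lay higher by a median of 0.42 (4 and 0 adjusted over the list alone, camera adjusted p = 0.0033, and adjusted p = 0.34 with an estimated correlation), and that call ended without 4C replicate 1 (adjusted p = 0.31). Ribosome biogenesis factors (69) lay lower by a median of -0.1 with 0 called (0 and 0 adjusted over the list alone, camera adjusted p = 0.0015, and adjusted p = 0.62 with an estimated correlation), a call that ended without 4C replicate 3 (adjusted p = 0.064). Primitive endoderm genes (19) lay higher by a median of 0.16 with 0 called (1 and 0 adjusted over the list alone, camera adjusted p = 0.045, and adjusted p = 0.39 with an estimated correlation). That call ended without 2C 2 (0.061), 2C 4 (0.083), 4C 1 (0.07), 4C 2 (0.065), 4C 3 (0.082), Morula 2 (0.055), MII 1 or 16C 3 (0.05 each).

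In limma 1329 genes had an unadjusted p under 0.05 in this contrast. The count rose when any of 17 libraries was left out: to 49 without 2C 1, 42 without 16C 3, 34 without 8C 4, 28 without 16C 1, 20 without 4C 1 or 16C 2, 18 without 8C 2, 12 without Morula 3, 9 without Morula 1, 8 without Morula 2, 6 without 4C 2, 5 without ExpB 2, 3 without 4C 3 or 8C 3, and 2 without 2C 2, 2C 3 or EarlyB 3.

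The step from 4C to 8C asked whether transcripts linked to genome activation were already present before the 16-cell stage. At 8C 91 genes were higher and 52 lower. ZSCAN4 rose from 6.11 ± 9.46 to 108 ± 92.7 (adjusted p = 0.0063), with 29.2 to 235 in the 8C libraries and 0 to 17.0 in the 4C libraries. SUPT4H1, a transcription elongation factor, rose from 5.82 ± 5.58 to 96.5 ± 72.4, PMAIP1, a p53 target that promotes apoptosis, from 8.62 ± 6.87 to 45 ± 21.5, and the signalling ligand WNT16 from 0.370 ± 0.323 to 4.42 ± 2.55. Among the genes that fell were the collagenase MMP1, from 18.9 ± 24.9 to 0.383 ± 0.343, BBOX1, an enzyme of carnitine synthesis, from 8.46 ± 5.27 to 0.766 ± 1.23, the cytokine receptor subunit IL6ST, from 14.7 ± 4.52 to 3.20 ± 1.61, and the cadherin CDH6, from 8.35 ± 6.4 to 1.2 ± 0.892. Without 4C replicate 1 the calls of all 8 ended, with adjusted p from 0.07 for ZSCAN4 to 0.21 for MMP1 and CDH6. Those of SUPT4H1, PMAIP1, MMP1, BBOX1, IL6ST and CDH6 ended also without 8C replicate 4 (adjusted p from 0.063 to 0.11), and those of BBOX1 and IL6ST without 4C replicate 3 (adjusted p = 0.063 and 0.069).

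Of the zygotic activation list ZSCAN4 was the called member among 21 (1 and 0 adjusted over the list alone, 0.02 in the median, camera adjusted p = 0.51, and adjusted p = 0.75 with an estimated correlation). KLF17 was at 0.183 ± 0.316 and 1.18 ± 0.794 and ARGFX at 0.399 ± 0.194 and 1.03 ± 0.901, neither of them called (adjusted p = 0.19 and 0.92). Oocyte genes (34) had 1 higher and 0 lower (1 and 0 adjusted over the list alone). At 8C the oocyte median difference was 0.33 (camera adjusted p = 0.0012, and adjusted p = 0.51 with an estimated correlation). The called one was YBX2, a germ cell RNA-binding protein, at 11.6 ± 1.96 and 29.6 ± 6.64. That call ended without 4C replicate 1, 8C replicate 2 or 8C replicate 4 (adjusted p = 0.16, 0.051 and 0.088). The 58 oxidative phosphorylation subunits lay lower with a median of -0.25 and 0 called (0 and 0 adjusted over the list alone, camera adjusted p = 0.00011, and adjusted p = 0.62 with an estimated correlation), a call that ended without 4C replicate 1 (adjusted p = 0.2). Cumulus and granulosa cell markers (16) had 0 higher and 2 lower (0 and 2 adjusted over the list alone). At 8C the cumulus marker median difference was -0.54 (camera adjusted p = 0.0015, and adjusted p = 0.31 with an estimated correlation). One of them, the follicle-stimulating hormone receptor FSHR, fell from 5.32 ± 0.974 to 1.08 ± 1.45, a call that ended without 4C replicate 1, 4C replicate 3, 8C replicate 3 or 8C replicate 4 (adjusted p = 0.17, 0.066, 0.057 and 0.11). These markers varied between libraries of a stage: LUM was at 289 in 4C 1, 122 in 4C 2 and 133 in 4C 3, and at 27.8, 82.7, 113 and 5.22 in 8C 1 to 8C 4, while TNFAIP6 was at 235 in 4C 1 and at most 5.20 in the other 4C and 8C libraries.

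**Figure D4:**
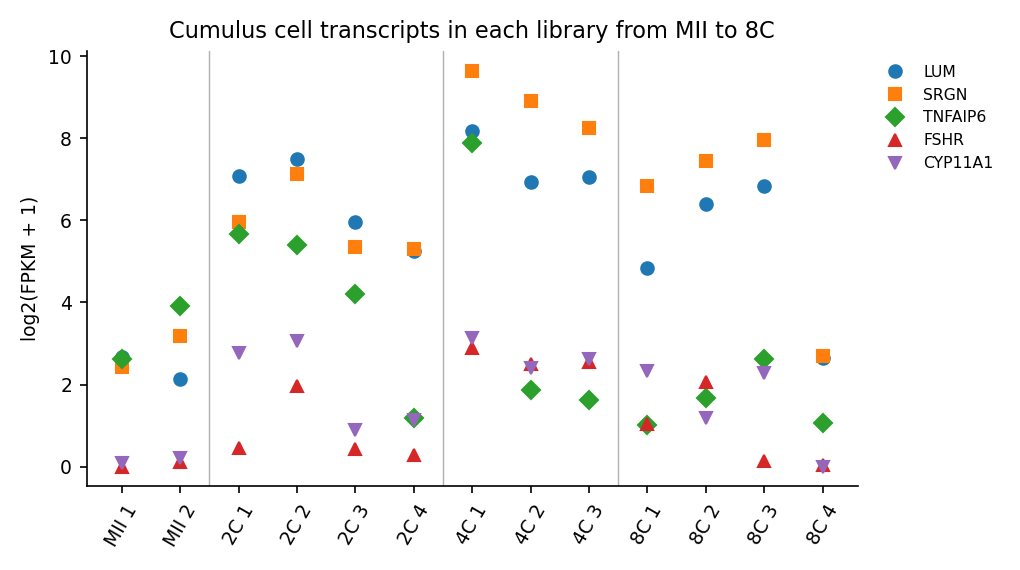
Levels of SRGN and 4 cumulus and granulosa cell markers as log2(FPKM + 1) in the 13 libraries from MII to 8C, 1 point per gene and library, with lines between stages. FPKM of LUM ranged from 3.41 in an MII library to 289 in 4C 1, and was at 5.22 in 8C 4.

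Single libraries moved the count: 6 genes were called without 4C 1, 12 without 8C 4, 77 without 4C 3, 217 without 8C 1, 231 without 4C 2 and 256 without 16C 3, and limma called 0 genes when only these 2 stages were fitted. With median-ratio scaling 52 genes were higher and 77 lower, and with quantile normalization 54 and 78.

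Embryos at 16C were compared with 8C to follow the known onset of embryonic transcription, and 874 genes were higher and 317 lower. The homeobox gene ARGFX rose from 1.03 ± 0.901 to 516 ± 780.3 (adjusted p = 4.8e-07), with 42.5, 88.9 and 1417 in the 3 16C libraries and at most 2.25 at 8C. KLF17, a Krüppel-like factor, rose from 1.18 ± 0.794 to 58.5 ± 10.6 (adjusted p = 3.2e-10), the KRAB zinc finger gene ZIM3 from 4.17 ± 5.56 to 347 ± 122 and TMEM37, a transmembrane protein, from 3.83 ± 2.92 to 503 ± 218. BECN2, a relative of the autophagy protein beclin, rose from 0.455 ± 0.528 to 115 ± 74.2 and the zinc finger gene ZCCHC10 from 4.02 ± 1.39 to 233 ± 103. Among the genes that fell were the cytokine IL24, from 4.52 ± 1.60 to 0.0515 ± 0.0893, NKIRAS1, an inhibitor of NF-kappa-B signalling, from 13.3 ± 2.29 to 2.88 ± 2.08, and SUDS3, a subunit of the SIN3 corepressor, from 9.11 ± 3.23 to 1.83 ± 1.33.

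The zygotic activation list (21 tested) had 11 higher and 0 lower (12 and 0 adjusted over the list alone). At 16C the activation gene median difference was 1.14 (camera adjusted p = 1e-09, and adjusted p = 0.0051 with an estimated correlation), 1 of 4 tests over all contrasts that passed both ways. Its higher members included OTX2, from 0.388 ± 0.278 to 12.8 ± 9.55, and SLC34A2, a phosphate transporter, from 0.0522 ± 0.0760 to 15.3 ± 20.5. ZSCAN4 was at 108 ± 92.7 and 263 ± 53 and was not called (adjusted p = 0.12). Of 67 SR proteins, hnRNPs and other splicing regulators there were 17 higher and 0 lower (17 and 0 adjusted over the list alone). At 16C the splicing regulator median difference was 0.38 (camera adjusted p = 1.4e-09, and adjusted p = 0.1 with an estimated correlation). The SR-like regulator TRA2B rose from 10 ± 4.86 to 109.7 ± 22.4, SRSF5 from 8.29 ± 1.32 to 63.7 ± 14.2, HNRNPAB from 1.65 ± 0.593 to 42.5 ± 16.8, HNRNPA2B1 from 26.4 ± 6.94 to 185 ± 29.0 and SRSF3 from 164 ± 24.5 to 667 ± 212. The core spliceosome had 13 higher and 1 lower of 85 (15 and 2 adjusted over the list alone) and a median difference of 0.04, which was -0.06 on the TPM scale and -0.03 with quantile normalization (camera adjusted p = 0.07, and adjusted p = 0.7 with an estimated correlation). BCAS2 of the PRP19 complex rose from 116 ± 32.8 to 474 ± 86.2 and the helicase DHX15 from 5.70 ± 1.40 to 35.8 ± 16.2. Cleavage and polyadenylation factors (29) had 2 higher and 1 lower (2 and 1 adjusted over the list alone, -0.07 in the median and 0.08 in the mean, camera adjusted p = 0.9, and adjusted p = 0.98 with an estimated correlation). RPRD1A, which binds the tail of RNA polymerase II, rose from 2.71 ± 0.541 to 41.5 ± 14.3.

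Ribosomal protein genes (76) had 38 higher and 0 lower (45 and 0 adjusted over the list alone). At 16C the ribosomal protein median difference was 1.22 (camera adjusted p = 4.6e-22, and adjusted p = 0.34 with an estimated correlation). FAU, the precursor of a small-subunit protein, rose from 48.1 ± 12.5 to 452 ± 94.6 and RPL26 from 8.86 ± 2.22 to 114 ± 90.9. Ribosome biogenesis factors (69) had 17 higher and 1 lower (18 and 1 adjusted over the list alone). At 16C the biogenesis factor median difference was 0.31 (camera adjusted p = 4.1e-05, and adjusted p = 0.51 with an estimated correlation). NOP16 went from 25.3 ± 6.57 to 414 ± 278. Pluripotency genes (22) had 4 higher and 0 lower (4 and 0 adjusted over the list alone). At 16C the pluripotency gene median difference was 0.21 (camera adjusted p = 0.0033, and adjusted p = 0.21 with an estimated correlation). PRDM14, a repressor linked to naive pluripotency, rose from 0.0652 ± 0.0970 to 12.8 ± 2.17 and ZFP42, also known as REX1, from 0.341 ± 0.255 to 46.6 ± 40.1. In the trophectoderm list (36) 2 members were higher and 1 lower (2 and 1 adjusted over the list alone, -0.02 in the median and 0.07 in the mean, camera adjusted p = 0.79, and adjusted p = 0.96 with an estimated correlation), and TFAP2C rose from 0.0471 ± 0.0192 to 16.3 ± 3.71. Oocyte genes (34) had 0 higher and 9 lower (0 and 9 adjusted over the list alone). At 16C the oocyte median difference was -0.71 (camera adjusted p = 1.4e-08, and adjusted p = 0.24 with an estimated correlation). NLRP5, a maternal-effect gene of the subcortical complex, fell from 2.46 ± 0.723 to 0.463 ± 0.181 and ACCSL from 462 ± 74.5 to 193 ± 16.9. BTG4 was at 1794 ± 147 at 16C and was not called (adjusted p = 0.31). Chromatin regulators (56) had 9 higher and 1 lower (9 and 1 adjusted over the list alone, -0.12 in the median and 0.07 in the mean, camera adjusted p = 0.93, and adjusted p = 0.98 with an estimated correlation). The deacetylase SIRT1 rose from 2.61 ± 0.934 to 21.4 ± 3.60 and the architectural protein CTCF from 8.47 ± 0.879 to 25.0 ± 7.21.

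With only these 2 stages fitted 316 genes were called, without ARGFX, SLC34A2, NKIRAS1 and SUDS3. On the TPM scale 998 were higher and 778 lower. Without 16C 3, 742 of the 1191 calls held.

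The wider comparison of 16C with 4C spans the window of genome activation, and it called 843 genes higher and 447 lower. ZSCAN4 rose from 6.11 ± 9.46 to 263 ± 53 (adjusted p = 3.5e-06), SUPT4H1 from 5.82 ± 5.58 to 414 ± 293 and ZIM3 from 0.902 ± 0.454 to 347 ± 122. BECN2 and PRDM14 were listed at 0 in every 4C library and stood at 115 ± 74.2 and 12.8 ± 2.17 at 16C. Among the genes that fell were the proteoglycan core protein gene SRGN, from 527 ± 252 to 31.0 ± 46.8, AMACR, a racemase of branched fatty acids, from 11.7 ± 4.17 to 0.881 ± 0.960, MMP1, from 18.9 ± 24.9 to 0.117 ± 0.190, and IGFBP3, a binding protein of insulin-like growth factors, from 11.9 ± 3.61 to 1.89 ± 2.56. The zygotic activation list (21) had 11 higher and 0 lower (11 and 0 adjusted over the list alone). At 16C the activation gene median difference was 1.2 (camera adjusted p = 3.2e-10, and adjusted p = 0.0051 with an estimated correlation). The test passed both ways. SR proteins and related regulators (67) had 14 higher and 0 lower (14 and 0 adjusted over the list alone). At 16C the splicing regulator median difference was 0.39 (camera adjusted p = 1.6e-07, and adjusted p = 0.13 with an estimated correlation). HNRNPA1 went from 65.6 ± 5.10 to 529 ± 204 and SRSF3 from 123 ± 2.51 to 667 ± 212. Ribosomal proteins (76) had 28 higher and 0 lower (41 and 0 adjusted over the list alone). At 16C the ribosomal protein median difference was 1.11 (camera adjusted p = 5.5e-18, and adjusted p = 0.41 with an estimated correlation). Ribosome biogenesis factors (69) had 17 higher and 2 lower (18 and 2 adjusted over the list alone). At 16C the biogenesis factor median difference was 0.4 (camera adjusted p = 1e-04, and adjusted p = 0.51 with an estimated correlation). That call ended without 16C 3 (adjusted p = 0.12). Oocyte genes (34) had 0 higher and 1 lower (0 and 1 adjusted over the list alone). At 16C the oocyte median difference was -0.43 (camera adjusted p = 0.0012, and adjusted p = 0.51 with an estimated correlation). That call ended without 16C 3 (adjusted p = 0.05). Pluripotency genes (22) had 5 higher and 1 lower (5 and 1 adjusted over the list alone). At 16C the pluripotency gene median difference was 0.21 (camera adjusted p = 0.0066, and adjusted p = 0.24 with an estimated correlation). Core spliceosome members (85) had 12 higher and 1 lower (15 and 2 adjusted over the list alone). At 16C the spliceosome median difference was 0.23 (camera adjusted p = 0.053, and adjusted p = 0.67 with an estimated correlation). SNRPB rose from 3.32 ± 0.0734 to 24.0 ± 8.37. Cumulus and granulosa cell markers (16) had 0 higher and 2 lower (0 and 2 adjusted over the list alone). At 16C the cumulus marker median difference was -0.46 (camera adjusted p = 0.045, and adjusted p = 0.51 with an estimated correlation). FSHR fell from 5.32 ± 0.974 to 0.515 ± 0.891, and the call of the list ended with median-ratio scaling (adjusted p = 0.059), a pseudocount of 0.1 (0.061), and without 4C 1 (0.27), 16C 1 (0.18), 16C 3 (0.05), Morula 1 (0.053), MII 1 (0.052) or MII 2 (0.051).

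With only these 2 stages fitted 162 genes were called, without ZSCAN4, SUPT4H1, SRGN, AMACR, MMP1, IGFBP3 and FSHR. On the TPM scale 953 were higher and 811 lower. Without 16C 3, 941 of the 1290 calls held.

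Morulae were compared with 16C embryos, the step with the most changed genes of the 8 contrasts in this fit: 4437 were higher and 2364 lower. GPX2, a glutathione peroxidase, rose from 0.845 ± 1.03 to 177 ± 110.4 (adjusted p = 6.5e-12), the iron hormone HAMP from 0.0833 ± 0.144 to 80.1 ± 50.6 (adjusted p = 1.8e-10) and the mitochondrial ribosome protein MRPL12 from 4.52 ± 5.66 to 171 ± 38.3. Among the genes that fell were the oocyte kinase WEE2, which inhibits CDK1, from 153 ± 55.6 to 7.0 ± 1.45 (adjusted p = 5.8e-11), BTG4, from 1794 ± 147 to 97.9 ± 19.1 (adjusted p = 9.4e-10), and TDRD7, a tudor protein of germ cell granules, from 90.8 ± 15.5 to 3.09 ± 0.696.

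Oocyte genes (34) had 0 higher and 29 lower (0 and 29 adjusted over the list alone). In morulae the oocyte median difference was -2.44 (camera adjusted p = 6.6e-14, and adjusted p = 0.11 with an estimated correlation). GDF9 fell from 508 ± 81.4 to 62.0 ± 9.89, ZP2 from 813 ± 258 to 116 ± 30.4, NPM2, a chromatin chaperone of the egg, from 42.1 ± 22.6 to 2.44 ± 1.60, and MOS, the kinase of the meiotic arrest, from 202 ± 79.1 to 43.2 ± 13.6. Nuclear-encoded oxidative phosphorylation subunits (58) had 52 higher and 1 lower (52 and 1 adjusted over the list alone). In morulae the respiratory subunit median difference was 2.64 (camera adjusted p = 5.6e-12, and adjusted p = 0.31 with an estimated correlation), while reads on mitochondrial protein genes went from between 1.19% and 1.81% to between 3.82% and 5.10%. NDUFA9 rose from 9.79 ± 6.81 to 180.2 ± 10.9 and ATP5PD of the ATP synthase from 53.2 ± 68.7 to 762 ± 76.4. Ribosomal proteins (76) had 71 higher and 0 lower (71 and 0 adjusted over the list alone). In morulae the ribosomal protein median difference was 2.42 (camera adjusted p = 2.5e-11, and adjusted p = 0.53 with an estimated correlation). RPLP2 rose from 88.9 ± 79.8 to 1507 ± 155 and RPL22 from 13.5 ± 10.8 to 266 ± 20.3. Ribosome biogenesis factors (69) had 30 higher and 2 lower (30 and 2 adjusted over the list alone). In morulae the biogenesis factor median difference was 0.81 (camera adjusted p = 0.019, and adjusted p = 0.7 with an estimated correlation). That call ended on the TPM scale (adjusted p = 0.094) and without 16C 1 (0.062), 16C 2 (0.062) or Morula 2 (0.052). MRTO4 rose from 4.4 ± 4.96 to 51.0 ± 4.25.

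Core spliceosome genes (85) had 36 higher and 3 lower (36 and 3 adjusted over the list alone). In morulae the spliceosome median difference was 0.85 (camera adjusted p = 0.028, and adjusted p = 0.66 with an estimated correlation). The spliceosome call ended on the TPM scale (adjusted p = 0.15), with median-ratio scaling (0.07) and without 16C 1 (0.06), 16C 2 (0.074) or Morula 2 (0.061). BUD31 rose from 30.9 ± 24.1 to 144 ± 33.4 and LSM3, an Sm-like protein of the U6 particle, from 422 ± 366 to 1608 ± 309. SR proteins and related regulators (67) had 20 higher and 7 lower (20 and 7 adjusted over the list alone). In morulae the splicing regulator median difference was 0.62 (camera adjusted p = 0.28, and adjusted p = 0.75 with an estimated correlation). Among them were the epithelial regulators ESRP2, from 0.533 ± 0.887 to 15.6 ± 2.50, and RBM47, from 0.493 ± 0.700 to 9.52 ± 1.3. Cleavage and polyadenylation factors (29) had 12 higher and 4 lower (12 and 4 adjusted over the list alone). In morulae the polyadenylation factor median difference was 0.65 (camera adjusted p = 0.28, and adjusted p = 0.67 with an estimated correlation). CPSF7 of cleavage factor I rose from 1.21 ± 0.376 to 13.9 ± 6.48, the termination factor PCF11 from 10.6 ± 1.88 to 44.4 ± 8.57, and CSTF1 of the cleavage stimulation factor fell from 489.9 ± 122 to 90.7 ± 8.12. The decay and storage list (59) had 13 higher and 14 lower (13 and 14 adjusted over the list alone), with a median of 0.38, a mean of 0.07 and a test direction of down (camera adjusted p = 0.56, and adjusted p = 0.83 with an estimated correlation). EXOSC4 of the exosome rose from 3.97 ± 1.45 to 44.4 ± 19.2, while the storage factors PATL2, from 13.3 ± 2.81 to 1.0 ± 0.0674, and EIF4E1B, from 24.5 ± 10.6 to 2.76 ± 0.336, fell. In the chromatin list (56) there were 18 higher and 9 lower (18 and 9 adjusted over the list alone). In morulae the chromatin regulator median difference was 0.46 (camera adjusted p = 0.93, and adjusted p = 0.98 with an estimated correlation), and KDM1B, a histone demethylase of the oocyte, fell from 27.5 ± 6.4 to 2.81 ± 0.347.

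Trophectoderm genes (36) had 14 higher and 1 lower (14 and 1 adjusted over the list alone). In morulae the trophectoderm median difference was 0.71 (camera adjusted p = 0.024, and adjusted p = 0.49 with an estimated correlation). That call ended without 16C 3 (adjusted p = 0.054). The tight junction gene CLDN6 rose from 1.78 ± 1.24 to 109 ± 36.2 and the keratin gene KRT8 from 1.27 ± 1.17 to 67.8 ± 16.1. Pluripotency genes (22) had 9 higher and 2 lower (9 and 2 adjusted over the list alone). In morulae the pluripotency gene median difference was 0.58 (camera adjusted p = 0.35, and adjusted p = 0.67 with an estimated correlation). POU5F1 rose from 2.59 ± 0.923 to 16.2 ± 4.82 and ESRRB from 0.0809 ± 0.109 to 7.45 ± 1.67. Stress response and p53 target genes (27) had 14 higher and 0 lower (15 and 0 adjusted over the list alone). In morulae the stress gene median difference was 1.04 (camera adjusted p = 0.042, and adjusted p = 0.26 with an estimated correlation). That call ended on the TPM scale (adjusted p = 0.08), with median-ratio scaling (0.06) and without 16C 3 (0.083) or Morula 2 (0.094). CDKN1A, an inhibitor of the cell cycle, rose from 3.52 ± 2.44 to 31.9 ± 8.86, and PHLDA3 from 0.0251 ± 0.0172 to 18.1 ± 6.79. In the zygotic activation list (21) there were 9 higher and 1 lower (9 and 1 adjusted over the list alone). In morulae the activation gene median difference was 0.97 (camera adjusted p = 0.11, and adjusted p = 0.5 with an estimated correlation). DUXB was listed at 0 in every 16C library and at 8.16 ± 1.47 in morulae. Of 16 cumulus and granulosa cell markers 2 were higher and 5 lower (2 and 5 adjusted over the list alone), with a median of -0.66 and a mean of 0.02 (camera adjusted p = 0.41, and adjusted p = 0.78 with an estimated correlation). VCAN fell from 9.28 ± 0.106 to 1.98 ± 1.35, and PTGS2, which also stands on the trophectoderm list, rose from 0.112 ± 0.178 to 25.8 ± 12.8. The sperm protamine PRM2 was listed at 0 in every 16C library and at 9.02 ± 0.837 in morulae, the called member of 9 tested sperm markers (1 and 0 adjusted over the list alone, camera adjusted p = 0.56, and adjusted p = 0.71 with an estimated correlation). Of 5 blood cell markers 1 was called higher (1 and 0 adjusted over the list alone, camera adjusted p = 0.39, and adjusted p = 0.62 with an estimated correlation). It was LYZ, from 1.10 ± 1.18 to 5.09 ± 3.66, whose values overlapped and whose call ended without 16C 2 (adjusted p = 0.1), Morula 1 (0.064) or Morula 2 (0.11) and on the TPM scale or with quantile normalization.

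The median of all genes was 0.32 as deposited, 0.18 with median-ratio scaling, 0.13 on the TPM scale and -0.01 with quantile normalization. The splits in the same order were 4437 and 2364, 3687 and 2716, 4353 and 3522, and 3054 and 3263, so that small differences of a list in this contrast are relative to that shift.

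Early blastocysts were compared with morulae to describe the formation of the trophectoderm, the outer epithelium, and of the inner cell mass. In EarlyB 2312 genes were higher and 1949 lower. KRT18 rose from 13.9 ± 6.4 to 582 ± 114 (adjusted p = 1.4e-11), KRT8, its keratin partner, from 67.8 ± 16.1 to 1531 ± 240.1 (adjusted p = 2e-08), and the membrane protease PRSS8 from 3.26 ± 1.84 to 81.6 ± 3.10 (adjusted p = 9.7e-12). The glycolytic enzyme gene GAPDH rose from 30.8 ± 6.46 to 498 ± 20.7. TMEM37 fell from 634 ± 174 to 18.8 ± 5.14 (adjusted p = 9.4e-08), ARGFX from 735 ± 291 to 71.8 ± 33.9 and UCHL1, a deubiquitinating enzyme of the oocyte, from 80.3 ± 57.7 to 5.71 ± 0.424.

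Trophectoderm genes (36) had 22 higher and 0 lower (22 and 0 adjusted over the list alone). In EarlyB the trophectoderm median difference was 1.61 (camera adjusted p = 6.9e-10, and adjusted p = 0.037 with an estimated correlation). The test passed both ways. GATA3 rose from 4.30 ± 1.37 to 36.5 ± 5.31, GATA2 from 0.611 ± 0.271 to 14.9 ± 4.26, KRT19 from 0.779 ± 0.670 to 23.6 ± 16.9 and CDX2 from 0.0119 ± 0.0207 to 2.32 ± 0.929. Primitive endoderm genes (19) had 11 higher and 1 lower (11 and 1 adjusted over the list alone). In EarlyB the endoderm gene median difference was 1.04 (camera adjusted p = 0.00015, and adjusted p = 0.11 with an estimated correlation). The apolipoprotein APOA1 rose from 0.258 ± 0.0421 to 17.0 ± 1.18, fibronectin FN1 from 2.56 ± 0.776 to 18.6 ± 7.09 and the laminin chain LAMA1 from 0.211 ± 0.152 to 5.10 ± 0.486. Pluripotency genes (22) had 6 higher and 1 lower (6 and 1 adjusted over the list alone). In EarlyB the pluripotency gene median difference was 0.47 (camera adjusted p = 0.45, and adjusted p = 0.72 with an estimated correlation). POU5F1 rose from 16.2 ± 4.82 to 48.0 ± 6.27, UTF1 from 0.883 ± 0.221 to 8.52 ± 1.74 and PRDM14 fell from 12.3 ± 2.66 to 4.34 ± 0.540. SOX2 was at 0.247 ± 0.231 and 1.36 ± 0.123, a difference of 0.93 that stayed under 1 (adjusted p = 2.5e-06). Ribosomal proteins (76) had 25 higher and 0 lower (24 and 0 adjusted over the list alone). In EarlyB the ribosomal protein median difference was 0.97 (camera adjusted p = 0.00048, and adjusted p = 0.75 with an estimated correlation). RPL13 rose from 279 ± 49.0 to 1308 ± 201.

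Zygotic activation genes (21) had 1 higher and 6 lower (1 and 6 adjusted over the list alone). In EarlyB the activation gene median difference was -0.56 (camera adjusted p = 0.41, and adjusted p = 0.7 with an estimated correlation). KLF17 fell from 60.7 ± 22.2 to 6.34 ± 4.99, and ZSCAN4 from 105 ± 51.0 to 20.7 ± 19.5, a call that ended without EarlyB 3 (adjusted p = 0.054), while TBX3 rose from 14.5 ± 1.27 to 59.9 ± 3.11. Oocyte genes (34) had 1 higher and 19 lower (1 and 19 adjusted over the list alone). In EarlyB the oocyte median difference was -1.26 (camera adjusted p = 1.6e-07, and adjusted p = 0.27 with an estimated correlation). BTG4 fell from 97.9 ± 19.1 to 9.85 ± 6.05 and ZP2 from 116 ± 30.4 to 25.5 ± 4.52. Core spliceosome genes (85) had 5 higher and 20 lower (5 and 20 adjusted over the list alone). In EarlyB the spliceosome median difference was -0.24 (camera adjusted p = 0.013, and adjusted p = 0.62 with an estimated correlation). MAGOH of the exon junction complex fell from 1671 ± 527 to 343 ± 41.0 and CWC15 from 561 ± 273 to 136 ± 28.6. SRSF3 fell from 789 ± 34.6 to 294 ± 50.9, in a list of 67 splicing regulators with 6 higher and 1 lower (6 and 1 adjusted over the list alone) and a median of 0.07 that was -0.04 on the TPM scale and -0.03 with median-ratio scaling (camera adjusted p = 0.99, and adjusted p = 1 with an estimated correlation). Cleavage and polyadenylation factors (29) had 1 higher and 6 lower (1 and 6 adjusted over the list alone). In EarlyB the polyadenylation factor median difference was -0.24 (camera adjusted p = 0.12, and adjusted p = 0.53 with an estimated correlation). NUDT21, which binds UGUA elements and guides poly(A) site choice, fell from 107 ± 25.1 to 27.1 ± 5.48 and the poly(A) polymerase PAPOLG from 33.8 ± 6.87 to 8.97 ± 0.608. Factors of RNA decay and storage (59) had 2 higher and 12 lower (2 and 12 adjusted over the list alone). In EarlyB the decay factor median difference was -0.45 (camera adjusted p = 0.0012, and adjusted p = 0.21 with an estimated correlation). EXOSC1 fell from 65.8 ± 13.0 to 12.2 ± 1.73. Chromatin regulators (56) had 12 higher and 6 lower (12 and 6 adjusted over the list alone). In EarlyB the chromatin regulator median difference was 0.4 (camera adjusted p = 0.21, and adjusted p = 0.62 with an estimated correlation). The reader UHRF2 fell from 66.4 ± 22.0 to 12.3 ± 1.40.

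With a pseudocount of 5 the count was 1909, without CDX2, LAMA1 and PRDM14.

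In ExpB, compared with EarlyB, 733 genes were higher and 2060 lower. WFDC2, a secreted protease inhibitor, rose from 0.842 ± 0.450 to 49.4 ± 19.8 (adjusted p = 5.2e-12), AKR1B1, an aldo-keto reductase, from 82.2 ± 2.69 to 1580.0 ± 388 (adjusted p = 9.6e-11), KRT19 from 23.6 ± 16.9 to 367 ± 146 and B2M, the light chain of MHC class I, from 7.87 ± 5.78 to 92.0 ± 31.4. Among the genes that fell were the activation and oocyte genes ARGFX, from 71.8 ± 33.9 to 3.88 ± 1.65 (adjusted p = 0.00017), ZSCAN4, from 20.7 ± 19.5 to 0.203 ± 0.364, KPNA7, from 21.2 ± 12.1 to 0.683 ± 0.471, ZP2, from 25.5 ± 4.52 to 1.39 ± 1.44, and ZP4, from 20.7 ± 9.47 to 0.776 ± 0.723.

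Primitive endoderm genes (19) had 6 higher and 0 lower (7 and 0 adjusted over the list alone). In ExpB the endoderm gene median difference was 0.63 (camera adjusted p = 3.4e-09, and adjusted p = 0.0062 with an estimated correlation). The test passed both ways. CITED1 rose from 2.52 ± 0.973 to 23.7 ± 5.45, LAMA1 from 5.10 ± 0.486 to 18.1 ± 2.84 and APOA1 from 17.0 ± 1.18 to 74.9 ± 11.8. SOX17 was at 0.128 ± 0.188 and 1.21 ± 0.434, a difference of 0.96, under 1 (adjusted p = 1.4e-05). GATA4, at 0.486 ± 0.249 and 1.095 ± 0.149, and GATA6, at 34.1 ± 1.27 and 27.8 ± 3.99, were not called. Trophectoderm genes (36) had 11 higher and 3 lower (11 and 3 adjusted over the list alone). In ExpB the trophectoderm median difference was 0.49 (camera adjusted p = 4.5e-06, and adjusted p = 0.13 with an estimated correlation). GATA3 rose from 36.5 ± 5.31 to 89.1 ± 11.5, and GATA2 fell from 14.9 ± 4.26 to 5.19 ± 3.64 with overlapping values. Pluripotency genes (22) had 2 higher and 3 lower (2 and 3 adjusted over the list alone), with a median of 0.04 and a mean of -0.07 (camera adjusted p = 0.43, and adjusted p = 0.71 with an estimated correlation). NANOG rose from 1.37 ± 0.536 to 19.6 ± 7.67, and KLF4 fell from 55.1 ± 6.4 to 10.8 ± 2.07, DPPA4 from 39.8 ± 5.25 to 11.4 ± 1.88 and SOX2 from 1.36 ± 0.123 to 0.0599 ± 0.0952. Among stress genes (27), the chaperones of the endoplasmic reticulum HSPA5 and HSP90B1 rose from 201 ± 25.4 to 2228 ± 334 and from 266 ± 26.3 to 1815 ± 209. That list had 2 higher and 3 lower (2 and 3 adjusted over the list alone), and its median of -0.05 was 0.33 with median-ratio scaling and 0.18 with quantile normalization (camera adjusted p = 0.17, and adjusted p = 0.48 with an estimated correlation).

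Oocyte genes (34) had 0 higher and 22 lower (0 and 22 adjusted over the list alone). In ExpB the oocyte median difference was -1.42 (camera adjusted p = 9.4e-09, and adjusted p = 0.24 with an estimated correlation). Ribosome biogenesis factors (69) had 0 higher and 23 lower (0 and 23 adjusted over the list alone). In ExpB the biogenesis factor median difference was -0.84 (camera adjusted p = 7.9e-06, and adjusted p = 0.48 with an estimated correlation). PES1 fell from 24.7 ± 2.35 to 5.82 ± 1.11 and the RNA acetyltransferase NAT10 from 16.1 ± 1.73 to 4.47 ± 0.505. Core spliceosome genes (85) had 0 higher and 23 lower (0 and 23 adjusted over the list alone). In ExpB the spliceosome median difference was -0.64 (camera adjusted p = 0.00065, and adjusted p = 0.48 with an estimated correlation). PRPF31 fell from 6.86 ± 1.3 to 1.44 ± 0.531 and SNRNP70 of the U1 particle from 7.37 ± 2.51 to 2.1 ± 1.83. Splicing regulators (67) had 1 higher and 11 lower (1 and 11 adjusted over the list alone). In ExpB the splicing regulator median difference was -0.36 (camera adjusted p = 0.53, and adjusted p = 0.9 with an estimated correlation). SRRM2 fell from 26.6 ± 1.66 to 6.77 ± 2.15. Cleavage and polyadenylation factors (29) had 0 higher and 6 lower (0 and 6 adjusted over the list alone). In ExpB the polyadenylation factor median difference was -0.55 (camera adjusted p = 0.37, and adjusted p = 0.7 with an estimated correlation). RBBP6 fell from 88.3 ± 10.6 to 30.0 ± 3.53. Factors of RNA decay and storage (59) had 0 higher and 11 lower (0 and 11 adjusted over the list alone). In ExpB the decay factor median difference was -0.64 (camera adjusted p = 0.0033, and adjusted p = 0.24 with an estimated correlation). The cytoplasmic polyadenylation factor CPEB1 fell from 8.90 ± 4.50 to 0.621 ± 0.691. Chromatin regulators (56) had 0 higher and 10 lower (0 and 10 adjusted over the list alone). In ExpB the chromatin regulator median difference was -0.56 (camera adjusted p = 0.002, and adjusted p = 0.24 with an estimated correlation). DOT1L, which methylates histone H3 in its core, fell from 6.50 ± 0.487 to 1.33 ± 0.349. Ribosomal proteins (76) had 0 higher and 9 lower (0 and 6 adjusted over the list alone), with a median of -0.54 while the test direction was up (camera adjusted p = 0.97, and adjusted p = 1 with an estimated correlation). RPS28 fell from 1314 ± 245 to 486 ± 294.

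The median of all genes was -0.3 as deposited, -0.08 with median-ratio scaling and -0.01 with quantile normalization, and the splits under those scalings were 1225 higher and 911 lower, and 1256 and 1049. With median-ratio scaling core spliceosome genes had 0 higher and 2 lower and ribosome biogenesis factors 0 and 9, and with quantile normalization SOX2 was no longer called.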

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

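In this part, the tests of library depth, of a morula library under a 16C label and of library scaling were chosen only after the result was seen, and the others were written down before. In the groups with 4 libraries, single values standing far from the other 3 of their stage were marked by Dixon's test of a gap at either end. It marked 8 of 111 groups, where chance (1 in 20 groups) would give 5.6. Marked for depth was ExpB 1, with 19.3 assigned reads in units of 1e6 against 24.4 to 25.4 in the other 3. Of the oocyte genes 3 were marked in ExpB 3, BMP15 at 2.143 against 0.0572 to 0.2287, ZP2 at 3.539 against 0.4905 to 0.7797 and MOS at 2.469 against 0.167 to 0.5278. In ExpB 1 GATA2 stood at 10.61 against 3.08 to 3.959 and DNMT3B at 58.23 against 23.72 to 26.75. At 8C, DNMT3A stood at 10.58 in 8C 3 against 12.34 to 12.53, and SNRPD1 at 242 in 8C 1 against 177.8 to 183.9. These libraries were kept in every comparison.

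The first pattern weighed is that 16C replicate 3 lay apart from the other 16C libraries, towards the morulae. Morula RNA mixed into the library would move genes higher and genes lower in morulae by the same share of the way, yet the median share was 0.125 over 4670 higher genes and 0.545 over 2740 lower genes, a difference of 0.42 (95% bootstrap interval 0.40 to 0.44, 2000 resamples), which argues against a plain mixture. A morula library carrying a 16C label is argued against by its highest correlation with a morula, 0.852, where the lowest between morulae was 0.940 and the highest of 16C 1 and 16C 2 with a morula were 0.744 and 0.764. Library depth is argued against by its 32.2 assigned reads in units of 1e6, between the 30.4 and 34.4 of the other 16C libraries. Embryos further along within the stage could give the same pattern, and stay open because no test here addresses them.

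The second pattern is the set of genes lower at 8C than at 4C. Carried-over cumulus or granulosa cells would make these genes follow cumulus markers between libraries of a stage. The 50 lower genes outside the marker list had a median within-stage correlation of 0.65 with its 16 tested members (13 libraries, MII to 8C). Matched random gene sets (10000) gave a median of 0.02 and a 95th percentile of 0.15, and the oocyte list gave -0.29, the trophectoderm list 0.07 and the ribosomal protein list 0.37. Library depth is argued against by the 4C median of 31.8 assigned reads in units of 1e6 beside 33.9 at 8C, with overlapping ranges. Decreases outside the list, such as MMP1 and IL6ST, might reflect a difference in carried-over cells. Regulation in the embryo stays open, since no cumulus cells were analysed. FSHR is on the list, so the 0.65 does not cover it.

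The third pattern is the number of genes changed between 16C embryos and morulae. Scaling of the libraries as its whole cause is argued against by the 6403 genes changed with median-ratio scaling, beside 6801 as deposited. Genomic DNA in the later libraries would raise genes silent in embryos, and the mean FPKM of 35 taste receptor, keratin-associated protein and beta-defensin genes went from 0.0509 at 16C (libraries 0.00664 to 0.0768) to 0.273 in morulae (0.157 to 0.453). That gain of 0.223 is small beside the median gain of 7.32 of the higher genes, so it may add to changes of genes near 0 but not to most of the count. These genes replaced olfactory receptors, none usable here, before any value was seen. Unspliced RNA stays open, as untranscribed genes cannot show it.

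Every split of the libraries of a pair of stages showed how many genes a wrong grouping calls. Between 4C and 2C, 8 of 35 splits called as many genes as the 1 of the real grouping, the highest other 35, so chance cannot be excluded. That highest split puts 2C replicate 1 with the 4C libraries, and whether the samples hold a structure other than the stage labels was not tested. For 8C minus 4C the real grouping was alone, 1 of 35 splits (143 genes, highest other 74). Chance stays open there, with 6 genes without 4C 1, 12 without 8C 4 and 0 with only these stages fitted. The same share, the lowest possible, argues against chance for 16C minus 8C (1191, highest other 532) and ExpB minus EarlyB (2793, 1637). The real grouping was also alone for Morula minus 16C (6801, highest other 1166), EarlyB minus Morula (4261, 98) and 16C minus 4C (1290, 122). Those had only 10 splits, too few to tell.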

How the results depend on the processing

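Here the tests with limma-voom on recovered reads were chosen only after the result was seen, and every other setting was written down before. Except where a cause is named, the cause of a shift was not tested. No named gene turned its direction under any setting, nor did a called list test under the settings run for lists, though some list medians near 0 changed sign with scaling.

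The pseudocount moved counts through genes of low FPKM, whose differences it shrinks or widens by construction. With a pseudocount of 5, 457 genes changed between 2C and MII (1017 as deposited), 7 between 4C and 2C (1), 43 between 8C and 4C (143), 555 between 16C and 8C (1191), 3491 between morulae and 16C (6801), 1909 between EarlyB and morulae (4261), 1000 between ExpB and EarlyB (2793) and 615 between 16C and 4C (1290). With a pseudocount of 0.1 the counts that moved were 11 for 4C minus 2C, 221 for 8C minus 4C, 1949 for 16C minus 8C and 4210 for ExpB minus EarlyB.

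Asking for an adjusted p alone, without a difference of at least 1, admits small differences by construction and gave 1738 genes for 2C minus MII, 2 for 4C minus 2C, 236 for 8C minus 4C, 2562 for 16C minus 8C, 7465 for EarlyB minus Morula, 6314 for ExpB minus EarlyB and 2307 for 16C minus 4C. When only the 2 stages were fitted, fewer libraries informed the variance, and 0 genes changed for 4C minus 2C, 0 for 8C minus 4C, 316 for 16C minus 8C and 162 for 16C minus 4C. The TPM scale gave 1624 genes for 2C minus MII. limma-voom on recovered reads gave 1981 for 16C minus 8C. No filter gave 87 for 8C minus 4C.

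The 1 gene changed between 4C and 2C became 3 with no filter, 16 with an FPKM of at least 1 in every library of a stage, 16 on the TPM scale, 41 with median-ratio scaling, 9 with quantile normalization, 300 with array weights and 15 with limma-voom on recovered reads. A count this unstable could owe as much to the setting as to the stages.

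Leaving out each library in turn gave between 212 (without MII replicate 1) and 1421 (without MII replicate 2) genes for 2C minus MII, 1 to 49 for 4C minus 2C (49 without 2C replicate 1) and 6 (without 4C replicate 1) to 256 (without 16C replicate 3) for 8C minus 4C. The ranges were 972 to 1773 for 16C minus 8C, 6317 to 7410 for Morula minus 16C, 4085 to 4413 for EarlyB minus Morula, 2618 to 2979 for ExpB minus EarlyB, 1092 to 1608 for 16C minus 4C and 43 to 50 for the gene list tests called. Genes first detected after 4C numbered 2912 to 3099 and maternal genes no longer detected 1234 to 1353, beside 2911 and 1232 with every library.

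The replicate block, which treats libraries of the same number as related, gave 81 genes for 8C minus 4C, and between 939 for 2C minus MII and 6806 for Morula minus 16C elsewhere, with 1 for 4C minus 2C. Of 422 calls of named genes 408 held. The replicate numbers do not pair the samples: correlations of same-number libraries after removal of the stage mean lay above 0.1 throughout only for 2C minus MII (0.14 to 0.40, 2 pairs), and between -0.15 and 0.23 in the other contrasts.

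Of 136 gene list tests 47 were called with a fixed correlation between genes, 4 with the correlation estimated per list, 44 on the TPM scale, 45 with median-ratio scaling and 49 with a pseudocount of 0.1. The lists are made of genes that vary together, and the ribosomal protein list had the highest estimated correlation of 0.605, so the fixed correlation likely makes its p-values too small. Of 422 calls of named genes, 355 held with a pseudocount of 5, 302 when only the 2 stages were fitted and 394 with median-ratio scaling. Leaving out a library ended from 2 to 34 of them, the most without MII replicate 1. Among the calls given in the report, limma-voom on recovered reads ended the calls of LUM and GSTA1 (2C minus MII), FSHR, SUPT4H1 and MMP1 (8C minus 4C) and LYZ (Morula minus 16C).

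Depth from 16.0 to 35.6 assigned reads per library, in units of 1e6, limits genes near an FPKM of 0, where single reads decide whether a gene is listed at 0, and the EarlyB libraries hold the fewest. Genes first detected after 4C numbered 2756 with a threshold of 0.5, 2776 with a threshold of 2 and 2259 on the TPM scale, and maternal genes no longer detected 1229, 1255 and 1458.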

Other observations

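Patterns here were chosen only after the result was seen, except the tests of cumulus carry-over and silent genes. The DNMT genes, TET3, ZSCAN4 and ARGFX were preset anchors with limma tests, not given here. DNA methyltransferase transcripts changed places. The maintenance enzyme DNMT1 stood at 843 ± 119 in MII oocytes, 326 ± 46.6 at 8C, 171 ± 67.7 at 16C, 13.1 ± 4.51 in morulae and 3.88 ± 0.679 in ExpB. The de novo enzyme DNMT3A went the other way, from 12.2 ± 4.13 in MII oocytes and 11.7 ± 3.13 at 16C to 66.9 ± 11.8 in morulae and 157 ± 32.0 in ExpB. DNMT3B was lowest in morulae, at 1.45 ± 0.474, and stood at 27.3 ± 5.72 in EarlyB. TET3, which oxidizes methylated cytosine, stood at 6.54 ± 0.259 in MII oocytes and 0.524 ± 0.268 in morulae.

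Small noncoding RNA genes, which poly(A) selection largely leaves out, drew more reads in the later libraries. Small nuclear and nucleolar RNA genes held 0.00088% to 0.00699% of reads from MII to 16C, 0.0325% to 0.0404% in morulae, 0.0515% to 0.0566% in EarlyB and 0.027% to 0.036% in ExpB. Their number with reads was 47 to 147 up to 16C, 337 to 380 in morulae and 431 to 447 in EarlyB. Transfer RNA genes held 0.00109% to 0.00204% of reads up to 16C, 0.00525% to 0.00672% in morulae and 0.0198% to 0.0304% in EarlyB. The 20 highest genes took 9.94% to 15.1% of reads from MII to Morula and 19.5% to 22.6% in blastocysts.

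Genomic DNA could raise the shares of the small RNA genes, with its gain of 0.223 FPKM of silent genes in morulae, as could transcription in the embryo, and neither was tested on them. ZSCAN4 was uneven between libraries at 4C, with 0, 1.32 and 17.0, and ARGFX at 16C, with 42.5, 88.9 and 1417, as was GCSH with 76.0, 105 and 2770, the highest in 16C replicate 3 for both ARGFX and GCSH.

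Carry-over of cumulus or granulosa cells, if it lies behind the correlation of 0.65, might also reach 2C embryos. There LUM stood at 134, 180, 61.1 and 37.4, beside 5.37 and 3.41 in the MII libraries. SRGN, which is outside the marker list, stood at 801, 477 and 305 in 4C 1 to 4C 3 and at 5.47 in 8C 4. The sum of FPKM also differed, with 419071 to 514805 from MII to 16C and 586848 to 682165 from morulae on. The difference of a gene between these sets of libraries therefore depends on whether FPKM or the TPM scale is used.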
